A study of Mus musculus with 4 samples.

How the data were processed

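ATAC-seq libraries were made from 50000 sorted LSK cells of mouse bone marrow each, 2 from p53+/+ and 2 from p53R248W/+ mice, and samples were grouped by the genotype in their labels. Intervals were called separately for each library, as each row of the deposited table carries the name of 1 library. Per the submitters' processing notes, MACS 1.4.2 and the genome build mm10 were used. The aligner, read filters, adjustment of read ends for transposase insertion, sequencing depth and signal normalization are not given in the sources used here. A different depth or signal scaling between libraries changes how many weak intervals are called, so an interval missing from a list is not evidence of closed chromatin.

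The deposited table held 220733 intervals. Per the file headers, it gives for each interval the highest-bin signal and the mean-bin signal, its length, and the CpG islands, promoters and genes assigned to it by the authors, with the distance from the summit to each gene's start. From the values, the bins were about 32 bases wide, and the highest-bin signal was a whole number from 16 to 1298. The authors' signal was used to describe, rank or filter intervals of each library's own list and not to test a difference between libraries, since no source gives a scaling that makes it comparable between them. The ranking by the lower signal of 2 libraries and the limit of 60 apply the same scale to libraries whose median signals were 52, 62, 62 and 50, so they can favor libraries with higher values. The authors' promoter window was wide: 100% of summits 5000 to 7000 bases upstream of a start, but 5.90% of those 8000 to 10000 bases upstream and 0.844% of those 4000 to 5000 bases downstream, carried a promoter annotation. Coordinates are those of the file on mm10. Length equaled end minus start in every row, so starts may be counted from 0. Gene coordinates of Trp53 came from a RefSeq table of the assembly GRCm38.p6, the same build.

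Because the table lists intervals per library and no value for every region in every sample, no per-region test of signal was made, and the tests planned for such values were not used. Intervals of the 4 libraries were merged with bedtools 2.31.1 where they shared at least 1 base, and each of the 69759 merged regions was scored as called or not called per library. A region was genotype-specific when called in both libraries of 1 genotype and in neither of the other. Its count was set beside those of the 2 other splits of the libraries, 2 against 2. Whole-library measures were compared by two-sided exact permutation tests, whose smallest possible p is 0.33. Shares of regions carry Wilson 95% intervals.

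The 14 gene lists, the main tests and the rule for named regions were set before the data were examined. A list gene counted as changed when a genotype-specific region was assigned to it by the authors, and its share was compared with all other genes with a region (20811 genes in total, 429 of 444 list genes, 6 matched by an older symbol) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 28 tests at 0.05. No p-value per gene exists here, so no count adjusted over the list alone could be given. Named regions were the 12 per direction with the highest minimum signal over the 2 libraries, and up to 4 members per list by the same measure. Trp53, Cdkn1a, Mdm2, Bax, Nlrp1a, Nlrp1b, Il1b and Ezh2 were read in every library. Other genes, such as Mllt3, are named to complete a small count. Some items that the rules select are not reported here. The comparison of start-site intervals shared by all 4 libraries, its examples (the members with the highest mean within-library percentile), the tests of CpG islands, the test of runs, the test of X without Firre and Dxz4 and the choice of X-linked and Y-linked genes were set after the data were seen.

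A run was 3 or more adjacent merged regions with the same pattern of calls. Its significance came from 10000 shuffles of the patterns among the regions of each chromosome. The counting and tests were tested on simulated data of 40492 regions, with 200 planted as R248W-only. The other regions had random loss of 5% of calls per library. The planted regions had none and were absent from both WT lists, so recovering all 200 checks the merging and counting only. There were 97 unplanted R248W-only regions, against 91 from random loss. Over 69759 regions, the run test, with fewer shuffles, fell under 0.05 in 1 of 100 simulations without planted runs. Regions were placed at random there, as the shuffles assume, so calls that cluster for other reasons were not checked.

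The alternatives were the best 50% of each list, the same number of intervals per library (46720), a reciprocal overlap of 50%, X and Y left out, each library left out in turn, other promoter windows, and promoter regions, other regions or the highest region per gene for the lists. Motif counts were not run, since no genome sequence was used here. Analyses used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.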

Results

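Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse bone marrow cells of the Lin-Sca1+Kit+ (LSK) gate, which holds hematopoietic stem and early progenitor cells. The study asked how a mutant form of the tumor suppressor p53 regulates transcription in these cells. It compared 2 libraries from wild-type p53+/+ mice (WT 1 and WT 2) with 2 libraries from mice carrying 1 mutant allele, p53R248W/+ (R248W 1 and R248W 2), each from 50000 cells. The deposited data listed each library's own accessible intervals, 46720 in WT 1, 62478 in WT 2, 60385 in R248W 1 and 51150 in R248W 2. They covered 61.2, 79.5, 79.3 and 64.7 Mb of the mm10 genome. Read depth was unknown. The labels did not say whether the 2 libraries of a genotype came from separate mice. For R248W, calls at the Y-linked genes examined below argue against a single mouse, with 4 of 4 called in R248W 1 and 0 in R248W 2. The spread between libraries may still be technical in part. Only the permutation tests of whole-library measures take in that spread. All other p-values take genes, regions or calls as units and do not measure it.

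The mean number of intervals was 54599 ± 11143 in WT and 55768 ± 6530 in R248W (SD, n = 2 libraries each). The difference did not exceed the spread between libraries (two-sided exact permutation test, p = 1, smallest possible 0.33), and the same p was obtained for covered length, median interval length and the promoter and CpG island shares. Merging all intervals that shared at least 1 base gave 69759 regions. Of these, 40492 (58.0%) were called in all 4 libraries.

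Start sites of p53 target, chromatin regulator, interferon, inflammatory and cell cycle genes were accessible in all 4 libraries more often than those of other genes. An interval with its summit within 1 kb of a transcription start site was present in all 4 libraries for 31 of 35 direct p53 target genes (88.6%), against 48.7% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 1.8e-05 over 14 lists). The highest-placed examples were Gadd45a, a stress-response gene, with highest-bin signals of 563, 902, 932 and 595 in WT 1, WT 2, R248W 1 and R248W 2, and Apaf1, the apoptosome scaffold, with 333, 575, 574 and 328. Polycomb and other chromatin regulators (28 of 35, exact adjusted p = 0.00116) included the start sites of Kdm6a, Ezh2, Eed and Asxl1. Interferon-stimulated genes (28 of 35, exact adjusted p = 0.00116) included Stat2, Cmpk2 and the RNA sensor Ifih1, NF-kappaB and inflammatory genes (24 of 32, exact adjusted p = 0.00916) included Ripk2, Relb and Birc3, and cell cycle genes (23 of 30, exact adjusted p = 0.00791) included E2f3, Ccna2 and Ccne1. The signals are the authors' values within each library's list and were not compared between libraries. The other genes were all remaining protein-coding genes, not matched for expression or CpG islands. The test therefore cannot tell a trait of these lists from one of active genes in general.

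Stem, lineage and developmental genes did not pass the same Fisher's exact test, apart from the mast cell, basophil and eosinophil markers. Start-site intervals in all 4 libraries were found for 20 of 40 stem cell genes (exact adjusted p = 1), among them Meis1 and Mycn, and for 18 of 29 inflammasome and interleukin-1 genes (exact adjusted p = 0.27), among them Il1rap and Irak4. They were found for 18 of 34 granulocyte and monocyte genes (exact adjusted p = 0.932), including Cebpa and Spi1, 15 of 30 lymphoid progenitor genes (exact adjusted p = 1), including Flt3 and Ikzf1, and 12 of 33 erythroid and megakaryocyte genes (exact adjusted p = 0.259), including Zfpm1 and Epor. Developmental regulators that are classical Polycomb targets had 17 of 47 (exact adjusted p = 0.188), including Tbx3 and Isl1, and stroma and endothelium markers 10 of 22 (exact adjusted p = 0.972), including Pdgfrb. Markers of mast cells, basophils and eosinophils had such intervals less often than other coding genes, 2 of 20 (10%, exact adjusted p = 0.0015). Mature T, NK and B cell markers had 7 of 26 (26.9%, exact adjusted p = 0.0601), and Cd3e, Cd8a, Lck and Ncr1 were among those with no start-site interval in any library. These counts take only summits within 1 kb of a start. By any assigned region, 37 of 40 stem cell genes had one called in all 4 libraries. So did 29 of 30 lymphoid progenitor genes and 21 of 26 mature lymphocyte markers. No comparison with other genes was made on this measure.

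To ask which regions were accessible in cells of 1 genotype only, regions called in both libraries of that genotype and in neither library of the other were collected. There were 857 R248W-only and 577 WT-only regions. The R248W-only regions with the highest signal lay at the promoter of Rbm38, which encodes an RNA-binding protein and is a known p53 target (chromosome 2, 173021221 to 173023413, summit 18 bases inside the gene, highest-bin signal 254 in R248W 1 and 169 in R248W 2), and upstream of Tango2 (chromosome 16, 18345066 to 18346040, 206 and 130). Another lay at the promoter of Nlrp1b, an inflammasome sensor (chromosome 11, 71230309 to 71231491, summit 147 bases upstream of the start, 138 and 80). The others were at Bola1 and Sv2a, LOC100861645, Irf2bpl, the calcium/calmodulin-dependent kinase gene Camk2g, Dgkg, Ldhd and Znrf1, Slc5a10, Gipc2 and a region with no assigned gene (chromosome 11, 71251013 to 71252188, 187 and 67).

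The WT-only regions with the highest signal lay upstream of Gsk3a, which encodes a glycogen synthase kinase (chromosome 7, 25239004 to 25240040, summit 1509 bases upstream, highest-bin signal 236 in WT 1 and 397 in WT 2), and at the promoter of Zkscan14 (chromosome 5, 145200866 to 145202474, 146 and 196). A WT-only region assigned to Hoxa7 and Hoxa9, homeobox genes of the stem cell program (chromosome 6, 52220921 to 52223040), had 102 and 146. Others were at Hs3st3b1, the RNA helicase gene Dhx9, Arhgap32, Fpgs and Eng, Exoc3l2 and Mark4, Gsto2, Hrh2 and a region with no assigned gene (chromosome 19, 9936184 to 9937348, 71 and 86). Many of these calls had a neighbor in the other genotype: 7 of the 12 R248W-only and 9 of the 12 WT-only regions lay within 2 kb of an interval of the other genotype, the WT interval next to the Rbm38 region being 326 bases away. The Nlrp1b region was 84913 bases from the nearest WT interval. In all 12 regions chosen in each direction, the intervals of the 2 libraries of that genotype met a reciprocal overlap of 50%. Absence from the other genotype could not change under this rule, since these regions share no base with its intervals.

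Genotype did not separate the libraries more than other groupings did. The genotype split gave 1434 specific regions in total, against 1786 for the split by replicate number (515 in WT 1 and R248W 1, 1271 in WT 2 and R248W 2) and 5314 for the remaining split (117 in WT 1 and R248W 2, 5197 in WT 2 and R248W 1). With the 46720 highest intervals of each library, the totals were 1661, 2019 and 2119. Only 3 such splits exist, so no p under 0.33 could be reached. The counts moved strongly with the libraries included. R248W-only regions numbered 1102 without WT 1, 6632 without WT 2, 2397 without R248W 1 and 4585 without R248W 2, and WT-only regions 5639, 1322, 3833 and 959. With signals of at least 60 in both libraries there were 19 R248W-only and 26 WT-only regions, the reverse order. Most genotype-specific regions were weak: the median of the lower of their 2 signals was 26 in both directions, against a median lowest signal of 53 for regions called in all 4 libraries.

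**Figure D1:**
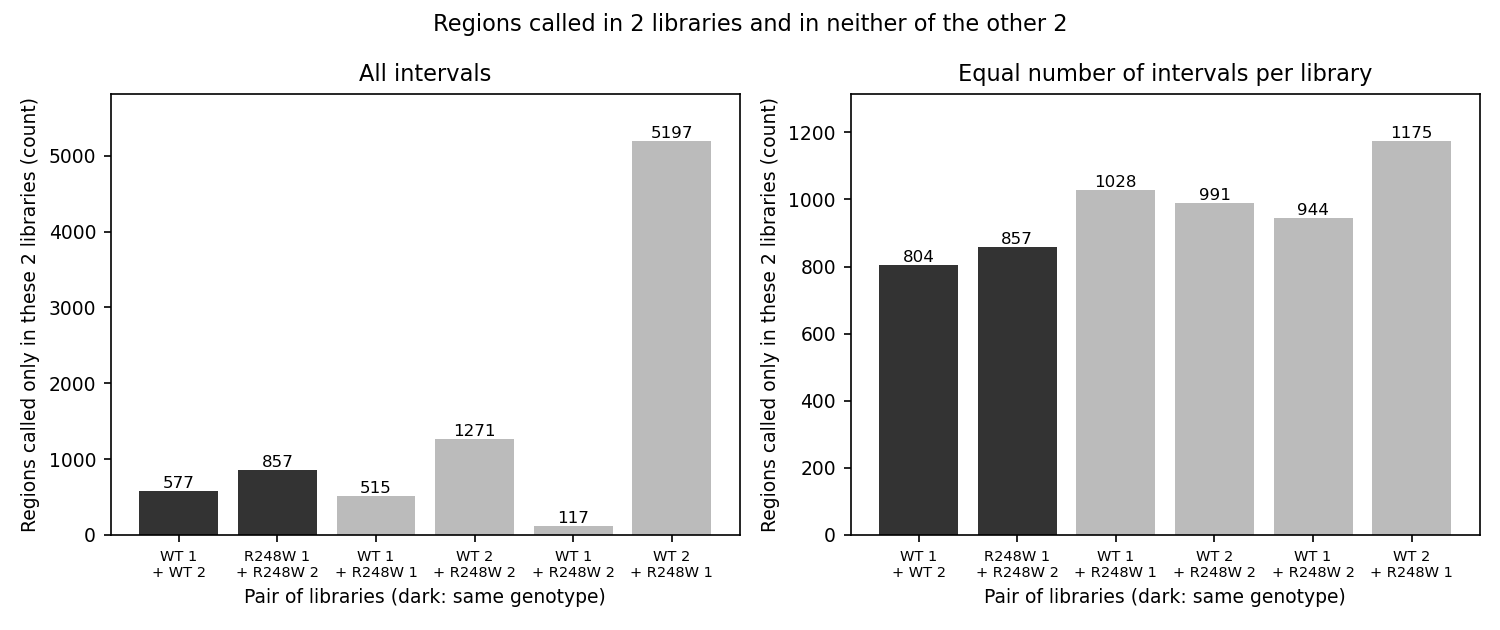
Number of regions called in a given pair of libraries and in neither of the other 2 (vertical axis, count; a bar per pair of libraries, dark for pairs of the same genotype), with all intervals (left) and with the same number of intervals per library (right). The same-genotype pairs have 577 and 857 regions on the left, below the 5197 of WT 2 and R248W 1, and 804 and 857 on the right, where the other 4 pairs have 944 to 1175. The 857 regions of the 2 panels are not the same set. Of 9 R248W-only regions in runs at Nlrp1b and the Trav genes on the left, 5 are R248W-only on the right.

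Direct p53 targets did not differ past the threshold from other genes in how many carried genotype-specific regions. Of the 35 listed targets, which do not include Rbm38, 1 had an R248W-only region (Bax, the pro-apoptotic effector, 10302 bases upstream, highest-bin signal 48 and 25 in R248W 1 and R248W 2) and 0 had a WT-only region. These shares of 2.86% and 0 stood against 3.68% and 2.33% of other genes (Fisher's exact test, adjusted p = 1 in both directions). With equal numbers of intervals per library 2 targets were R248W-only and 2 WT-only, and Bax was not among them. Among the genes checked in every library, Trp53, Cdkn1a and Mdm2 had no genotype-specific region. The highest signals assigned to Trp53 were 169, 222, 221 and 177 in WT 1, WT 2, R248W 1 and R248W 2, those of the cell cycle inhibitor gene Cdkn1a 169, 259, 268 and 196, those of the p53 ubiquitin ligase gene Mdm2 216, 328, 328 and 241, and those of Bax 237, 395, 425 and 254. Ezh2, the Polycomb methyltransferase, had 282, 489, 463 and 299, Il1b had 147, 235, 237 and 184, and the start of Nlrp1a, next to Nlrp1b, had 82, 113, 183 and 80. Not all of these values lay at start sites. Cdkn1a and Il1b had no interval with its summit within 1 kb of a start in any library, and Trp53 had none in R248W 2. Both Trp53 regions were nevertheless called in all 4 libraries, so the summit position and not a missing call set R248W 2 apart. Bax had 68, 68, 64 and 55 at its start.

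Single inflammasome, interferon and NF-kappaB genes had genotype-specific regions, with no list past the adjusted threshold. R248W-only regions lay at 2 of 29 inflammasome and interleukin-1 genes, Nlrp1b and the decoy receptor gene Il1r2 (37 and 29), and at 2 of 35 interferon-stimulated genes, Oas3 (37 bases upstream of its start, 96 and 60) and Stat2 (26 and 26). WT-only regions lay at 3 of 32 NF-kappaB and inflammatory genes, the chemokine gene Ccl5 (35 and 33 in WT 1 and WT 2), Nfkb1 (25 and 27) and Il6ra (22 and 29), or 9.38% of the list against 2.32% of other genes (Fisher's exact test, unadjusted p = 0.0379, adjusted p = 0.53). The same inflammasome and interferon lists had 0 WT-only members, and the NF-kappaB list 0 R248W-only members. With equal numbers of intervals per library the NF-kappaB list had 0 of 31 in either direction and the interferon list 1 R248W-only (Oas3) and 3 WT-only members, so no direction held for these 2 lists, while Nlrp1b and Il1r2 remained R248W-only.

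Stem cell genes had WT-only regions at 3 of 40 members, Hoxa9, Fli1 (36 and 52) and Mllt3, and R248W-only regions at 2, the transcription factor genes Prdm16 (27 and 38) and Mecom (31 and 26). Lymphoid progenitor genes had WT-only regions at 3 of 30 members, Bcl11b (32 and 37), Foxo1 (32 and 47) and Ccr7 (28 and 35), or 10% against 2.32% of other genes (Fisher's exact test, unadjusted p = 0.0321, adjusted p = 0.53), and R248W-only regions at 0. Granulocyte and monocyte genes had 0 of 33 in either direction. Erythroid and megakaryocyte genes had WT-only regions at Ermap and Cd36 and an R248W-only region at Zfpm1, of 28 members with any region. Cell cycle genes had WT-only regions at 2 of 30, Cdk6 (60 and 106) and Ccnd2 (25 and 30), and R248W-only regions at 0.

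Chromatin regulators had WT-only regions at Kdm6a and Kat6a and an R248W-only region at Tet1, of 35. Polycomb-target developmental genes had R248W-only regions at Gata4 and Hand1 and a WT-only region at Pax3, of 47. Among markers of other cell types, WT-only regions lay at Cd247 (1 of 23 mature lymphocyte markers), Mcpt8 (1 of 15 mast cell, basophil and eosinophil markers) and Sp7 and Runx2 (2 of 21 stromal and endothelial markers), and Runx2 also had an R248W-only region. None of the 28 list tests passed (Fisher's exact test, two-sided, Benjamini-Hochberg, smallest adjusted p = 0.53), and 2 had an unadjusted p under 0.05. A gene with more regions can more easily hold a specific one. Counted by region, 3 of 168 lymphoid and 3 of 107 NF-kappaB regions were WT-only (Fisher's exact test, unadjusted p = 0.163 and 0.0595). Without R248W 1, the lymphoid list passed in the WT-only direction, with 11 of 30 genes against 13.4% of other genes (exact adjusted p = 0.0334). Of the 32 pairs of a list member and a direction, 10 were found again with equal numbers of intervals per library. Over the planned and added alternatives the smallest adjusted p ranged from 0.0334 to 1.

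Genotype-specific regions lay mostly away from promoters, as did other regions not called in every library. By the authors' promoter annotation, 17.9% of R248W-only regions (Wilson 95% interval 15.4 to 20.6%) and 16.6% of WT-only regions (13.8 to 19.9%) were at promoters, against 37.3% (36.9 to 37.8%) of the regions called in all 4 libraries and 15.2% of the other regions called in 1 to 3 libraries. Neither direction differed from the latter past the threshold (Fisher's exact test, adjusted p = 0.102 and 0.524). The difference between the 2 directions did not pass (Fisher's exact test, adjusted p = 0.733). With summits within 1 kb of a start the shares of R248W-only, WT-only and shared regions were 6.42, 4.51 and 28.4%. CpG islands were present at 6.88% of R248W-only and 3.64% of WT-only regions (exact adjusted p = 0.0428), and at 4.08% of the other regions called in 1 to 3 libraries. With equal numbers of intervals per library this difference did not pass, at 5.60% and 3.61% (exact adjusted p = 0.149), and the other regions had 5.75%. These intervals and tests take regions as units and cover counting error only. Per library, promoters made up 34.4, 29.6, 30.0 and 33.2% of the intervals of WT 1, WT 2, R248W 1 and R248W 2, with lower shares in the longer lists.

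R248W-only regions formed runs at Nlrp1b and in the T cell receptor alpha locus. A run of 3 adjacent regions spanned the start of Nlrp1b and its upstream flank (chromosome 11, 71230309 to 71285670, highest-bin signals 37 to 187). Both WT libraries had no interval between 71145458 and 71669950, a stretch of 524 kb in which R248W 1 had 4 and R248W 2 had 3. In the variable gene segments of Tcra, 2 runs of 3 regions each had weaker signals. They lay at Trav13d-3 to Trav14d-3-dv8 (chromosome 14, 53041704 to 53073819, signals 24 to 53) and at Trav10n to Trav11n (53121612 to 53135387, signals 26 to 32). Both were within a stretch of 534 kb that had 9 intervals in R248W 1, 7 in R248W 2 and 0 in WT 1 and WT 2. A further run lay at Rapgefl1 and Wipf2 (chromosome 11, 98849037 to 98859796, signals 20 to 47).

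These 4 runs held 12 regions, against a mean of 0.393 when the calls were shuffled within chromosomes (permutation test, 10000 shuffles, p = 0.0001, the smallest they can give, adjusted p = 0.0003 over 6 pairs of libraries). WT-only regions formed 0 runs. The pair WT 2 and R248W 2, of different genotypes, had 24 regions in runs with the same p and adjusted p, so the test was not particular to R248W. With equal numbers of intervals per library only the 3 regions at Nlrp1b formed a run (permutation p = 0.161). As 3 regions are the fewest a run can hold, this p gives how often shuffles had any run at all. It uses neither signal nor place, so it cannot decide for Nlrp1b alone. Nlrp1b lies 1.64 Mb from Trp53 on chromosome 11, and the labels did not give the strain of either genotype. Within 5 Mb of Trp53, 5 of 390 regions were specific to a genotype (1.28%), against 2.06% elsewhere (Fisher's exact test, p = 0.369).

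**Figure D2:**
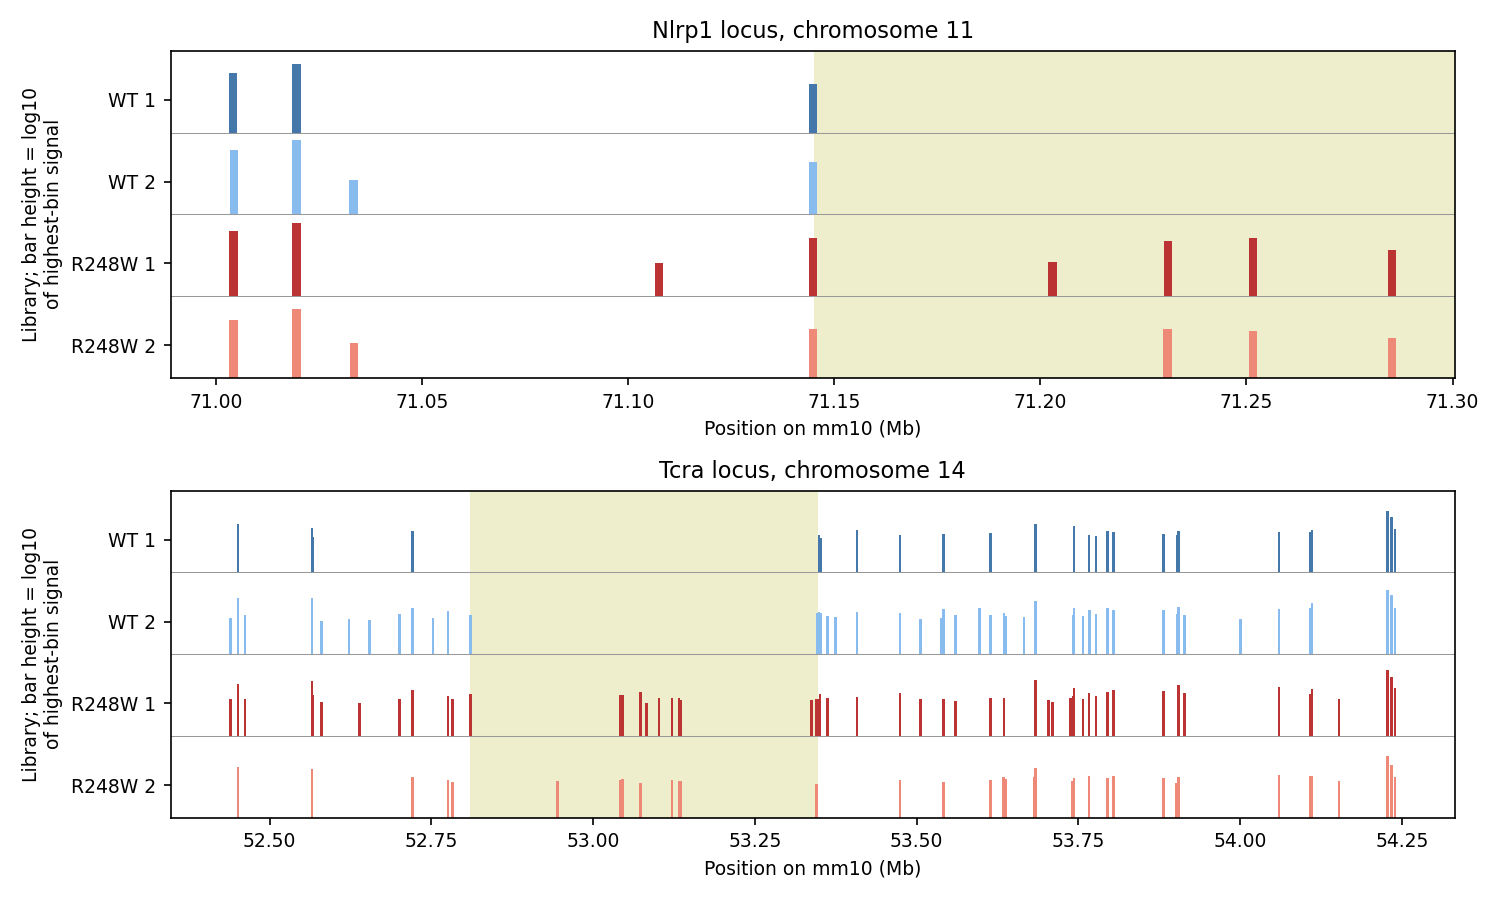
Intervals of each library along chromosome 11 at Nlrp1a and Nlrp1b (top) and along chromosome 14 at Tcra (bottom), with position in Mb of mm10 on the horizontal axis and a row per library; bar height is the log10 of the highest-bin signal. In the shaded stretches, the upper of which runs on beyond the plotted range to 71669950, R248W 1 has 4 and 9 intervals, R248W 2 has 3 and 7, and both WT libraries have 0.

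At the X-linked loci Firre and Dxz4 the libraries differed by replicate number and not by genotype, while at Y-linked genes R248W 2 stood apart. Firre, listed as 6720401G13Rik, an X-linked gene with a repeat locus, had 17 intervals in WT 2 and 16 in R248W 2 but 1 in WT 1 and 1 in R248W 1. The X-linked repeat locus Dxz4, listed as 4933407K13Rik, had 7 in WT 2, 7 in R248W 2 and 1 in each of the other libraries. Xist, the X inactivation RNA gene, had 2, 3, 2 and 4 intervals in WT 1, WT 2, R248W 1 and R248W 2. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y all had an interval in WT 1 and R248W 1, 3 of them had one in WT 2 (not Kdm5d), and 0 had one in R248W 2. All 6 Y intervals of R248W 2 lay beyond 50 Mb, at the end of Y that holds Mid1 and Erdr1, where WT 1 had 6, WT 2 7 and R248W 1 7, and before 50 Mb the libraries had 7, 4, 8 and 0. Of 1721 regions on X, 53 (3.08%) were called only in WT 2 and R248W 2, against 1.79% of regions elsewhere (Fisher's exact test, adjusted p = 0.00511). Firre and Dxz4 held 21 of the 53, and in the rest of X the excess did not pass (32 of 1697, 1.89%, Fisher's exact test, p = 0.711). No chromosome passed for the R248W-only or WT-only regions. Without X and Y there were 834 R248W-only and 557 WT-only regions.

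**Figure D3:**
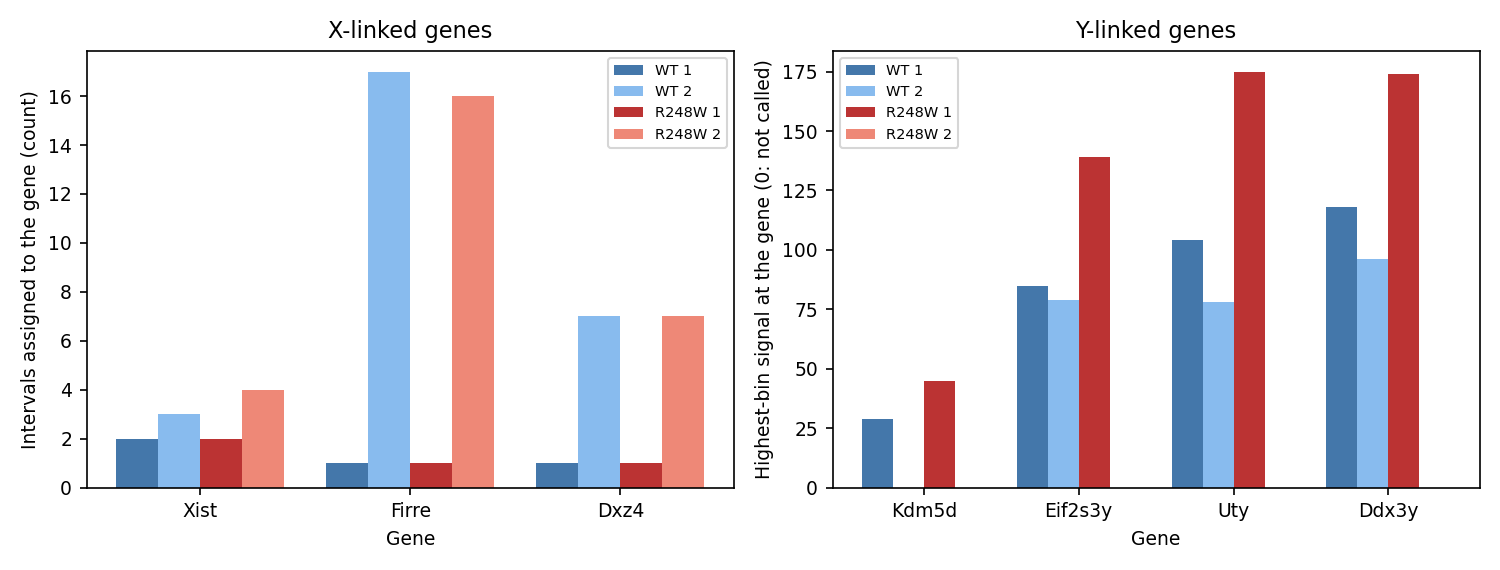
Number of intervals assigned to 3 X-linked genes (left, count) and highest-bin signal at 4 Y-linked genes (right, 0 where no interval was called), a bar per library. Firre has 17 and 16 intervals in WT 2 and R248W 2 and 1 in each other library, and R248W 2 has no interval at the Y-linked genes.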

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

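The strong-call limit, the 1 kb window, the promoter shares with equal lists or without a library, and the list tests by region or with equal lists were chosen after seeing the data; the other alternatives were planned. In every setting for which the 3 splits were counted, both other splits gave more specific regions than genotype. The best 50% of each list gave 368 R248W-only regions of 616 in both directions, a smaller count because fewer intervals entered. Calls with signals of at least 60 gave 19 R248W-only and 26 WT-only regions, 45 in all, so that the order of the 2 directions turned; the cause was not tested. Leaving out a library gave 1102 to 6632 R248W-only regions and 5544 to 7954 in both directions, since fewer lists then have to hold or lack a region. The promoter share of all regions, R248W-only and WT-only regions was 21.5, 10.7 and 8.32% with summits within 2.5 kb of a start, 18.6, 6.42 and 4.51% within 1 kb, and 13.2, 4.08 and 2.95% up to 1 kb upstream, all narrower windows than the authors'. Leaving out a library gave promoter shares of 14.7 to 17.9% for R248W-only and 14.3 to 19.5% for WT-only regions. Lists past the threshold numbered 0 to 1 when a library was left out and 0 in the other settings. Among the alternative values, 31 stayed within the spread set for them and 22 moved. No paired analysis was possible because the region counts come from no test on values that could carry a replicate block; regions called in both R248W libraries and neither WT library are the same with any pairing. Motif alternatives and those for a test on values (normalization, pseudocount, low values, variance model, measure, threshold, tool, replicate block, inter-gene correlation) were not run. Unknown read depth limits what a missing call means, above all in WT 1. WT 1 lacked 153 of 18093 regions (0.846%) that the other 3 libraries called and whose intervals all had signals of at least 60. Regions that WT 1 called with a signal below 60 were left out of this count.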

Other observations

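The count of specific regions with the same number of intervals per library was planned, and the other tests in this part were chosen after their results were seen.

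Some genes had several specific regions: 37 genes had 2 or more R248W-only regions and 7 had 2 or more WT-only regions, among 765 and 485 genes with any. Tcra had 8 R248W-only and 1 WT-only of 65 regions, and some of the 37 genes are Trav segments counted with the same regions. Runs shared by WT 2 and R248W 2 lay at Firre (7 and 8 adjacent regions), at Dxz4 (6) and on chromosome 4 at 6330411D24Rik (142792316 to 142910114, 3 regions).

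Shorter lists in both WT libraries are argued against as the source of the R248W-only runs at Nlrp1b and in the Trav genes of Tcra, since WT 2 had the longest list of all (62478 intervals) and no interval in either stretch. A shorter list in WT 1 is argued against at Nlrp1b, where all 3 regions stayed R248W-only with every list cut to the length of that of WT 1, and stays open at the Trav genes, where 2 of 6 did. Chance placement was not settled by the shuffles and stays open. They gave as many regions in runs with permutation p = 0.0001, the smallest they can give, with all intervals, but p = 0.161 with equal lists. The latter only gives how often shuffles had any run, so it cannot decide for a single locus. Linked or strain DNA may also account for the Nlrp1b run, since Nlrp1b varies between inbred strains and lies 1.64 Mb from Trp53; specific regions were not enriched within 5 Mb of Trp53 (odds ratio 0.617), which does not exclude a segment that differs at few places. It cannot be told apart from an effect of mutant p53 at Nlrp1b, as the 2 go together in these libraries, and a strain difference at the Trav genes was not tested and stays open.

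The 5197 regions called only in WT 2 and R248W 1 may come from the longer lists of these libraries. With the same number of intervals per library, 1175 regions were called only in these 2, a fall that a difference in list length predicts. The cut shortens these 2 lists most, so such a fall cannot tell why their lists were longer. The 1175 was still the highest count of any pair. WT 2 and R248W 1 also still shared the most regions (82.1% of those in either), against 74.3 to 78.4% for the other pairs. A difference in depth or signal scaling between libraries is a candidate source, and the labels give neither. No biological explanation was tested, because the pair crosses the genotypes.

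The intervals at Firre and Dxz4 in WT 2 and R248W 2 were weighed last, and they carried the excess of such regions on X. Both loci are known to be open on the inactive X. Female cells in R248W 2 and male cells in WT 1 and R248W 1 are consistent with the Y-linked genes, of which 0 were called in R248W 2 and 4 in each of the other 2; the 6 Y intervals of R248W 2 lay at Mid1 and Erdr1, by the pseudoautosomal end that X shares, and the interval counts at Xist (2, 3, 2 and 4) add little. Female cells alone are argued against in WT 2, where 3 of 4 Y-linked genes were called, so a mixture of male and female cells may be the source there. The labels give no sex, and a part of the autosomal specific regions could go with sex, which was not tested.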
